A study of Homo sapiens with 6 samples.

How the data were processed

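The samples are 6 pieces of tissue-engineered small intestine (TESI), each measured once by bulk sequencing of total RNA. Per the labels, human embryonic stem cells were differentiated to human intestinal organoids (HIO) of day 28 to 35, and 4 to 6 organoids were seeded on a biodegradable polymer scaffold and grown for 3 months in the mouse omentum. In 3 samples (ENCC-HIO-TESI, replicates 2, 3 and 5) the scaffold also received 40 to 60 unsorted enteric neural crest cells (ENCC) of day 15, made from embryonic stem cells. The other 3 samples (HIO-TESI, replicates B, D and E) received organoids alone. Tissue was lysed in RNAlater, RNA was purified on Qiagen RNeasy columns, and libraries were made with Illumina TruSeq v2. The labels name no sequencing batch, day, animal or organoid preparation, so no batch could be modelled. The sample titles of HIO-TESI carry the tag H9, which those of ENCC-HIO-TESI lack. A difference in cell line or series between the groups therefore cannot be excluded. Nothing in the labels says that replicates are separate cultures or animals, so p-values measure only the spread between these samples.

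Per the submitters' processing notes, the tools were cutadapt 1.13, Trimmomatic 0.35, STAR 2.5.2b, HTSeq 0.6.1p2 and edgeR 3.16.5, with the genome build GRCh38. Their options, the annotation release and the strand setting are not given in the sources used here, so overlapping genes on opposite strands cannot be told apart. Reads of host mouse cells were not separated from human reads as far as those notes say.

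The deposited table holds 43566 genes. Per the file headers, it gives a raw count for each gene and sample, and the values are whole numbers. The authors also give an RPKM per gene and sample, which equals the count divided by the deposited gene length and by an effective library size. That size was 0.941 to 1.06 times the total count of the sample. The authors' own comparison of the groups is given as a log2 fold change and a mean log2 CPM per gene, positive where ENCC-HIO-TESI is higher. The authors' score for each gene is a likelihood ratio statistic, per the file headers. The authors' p-value is given per gene with an adjusted p, which equals the Benjamini-Hochberg value over all genes of the deposited table. Their model and covariates are not given in the sources used here. The counts were analysed anew, and the authors' comparison is quoted only where it is named.

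Gene symbols were taken from the deposited table. Gene class and coordinates came from GENCODE 29, matched by Ensembl identifier for 43192 genes, which is 99.1% of the table. That copy of the annotation may differ from the one the authors used. In the table, 2878 genes had no count in any library.

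Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which asks for that level in 3 libraries, and 20372 genes remained. A gene seen in only 2 libraries of a group is therefore left out of this test, and such genes are described by their values. Libraries were scaled by TMM, and the quasi-likelihood F test compared ENCC-HIO-TESI with HIO-TESI without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Values per library are CPM, the usual scaled counts, over the TMM-scaled library size, and group values are means with SD over 3 libraries. Log2 fold changes are ENCC-HIO-TESI over HIO-TESI, and their standard error (SE) is the fold change divided by the square root of F. DESeq2 1.42.0 and limma 3.58.1 (voom) were run on the same counts.

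Total counts per library ran from 26068396 to 40255638. A count of 0 allows up to 3 counts, which is between 0.074 and 0.112 CPM. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Folds are not given against a group with 0 to 3 counts.

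The comparison, the test, the alternatives, 37 gene lists and the rule for naming genes were written before the data were examined. The lists hold 578 entries for 566 genes, of which 560 are in the table. They cover enteric neural crest, pan-neuronal genes, enteric neuron subtypes, glia and Schwann cells, signalling to the enteric nervous system (ENS), smooth muscle, interstitial cells of Cajal with PDGFRA cells, fibroblasts and matrix, pan-epithelial intestinal genes, enterocytes, goblet cells, Paneth cells, enteroendocrine cells, intestinal stem cells, proliferation, brush border digestion and lipid transport, stomach and foregut, colon and HOX genes. Further lists cover cartilage and bone, melanocytes, skeletal muscle, central nervous system, pluripotency, endothelium, blood and immune cells, adipocytes and mesothelium, skin and squamous epithelium, liver and pancreas, lung and thyroid, kidney, heart muscle, stress and immediate early genes, hypoxia, interferon response, inflammation and mitochondrially encoded genes. The 32 lists with at least 5 tested members were tested as sets with camera at its preset correlation of 0.01, adjusted over the lists. Members were also adjusted over the list alone.

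Genes are named by this rule: 11 fixed neural crest, neuronal and glial markers; the 10 higher and 10 lower protein-coding genes with the largest fold change among those called, at a mean of at least 1 CPM and with no overlap between groups; and up to 4 members of each list with the smallest p. No gene passed the called part of the rule, so it was applied to the authors' calls instead, a choice made after the result was seen. Some genes that the rule names are not reported here. Other genes named were chosen after their values were seen. After the data were seen, 4 lists were added: choroid plexus, retinal pigment epithelium, motile cilia and pancreatic acinar cells. For these, members at least 4-fold above every HIO-TESI library were counted in each ENCC-HIO-TESI library with HIO-TESI values under 1 CPM raised to 1. Because these lists were written after the data were seen, their counts describe the libraries and test nothing. The same counts at 2-fold describe the fixed lists. Means of log2 CPM relative to pan-epithelial genes were taken after adding 0.01 CPM.

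The alternatives were RLE, upper-quartile and total-count scaling, no filter, a stricter filter of at least 1 CPM in at least 3 libraries, protein-coding genes only, 1 unwanted factor estimated from 5000 control genes, each library left out, DESeq2, limma-voom, stricter thresholds, camera with an estimated correlation, and fry. Alternatives chosen after seeing the data were the edgeR likelihood ratio test, the quasi-likelihood test with its newer deviances, a filter of 10 counts in 2 libraries, and 2 combinations without ENCC-HIO-TESI replicate 2. No paired analysis was possible because the replicate labels of the groups do not match.

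The tests were tried on simulated data with 3 libraries per group and 200 changed genes, in 3 simulations with the dispersions of these libraries. The quasi-likelihood test recovered 34.8% of genes changed 2-fold, 80.6% at 4-fold and 94.4% at 8-fold, and 6.67% of its calls were unchanged genes. Voom recovered 31.8%, 81.1% and 93.4%, with 7.17% of calls unchanged. DESeq2 recovered 55.2%, 88.1% and 97.0%, with 26.5% of calls unchanged, and the likelihood ratio test 51.2%, 92.5% and 99.5%, with 24.3%. All genes were drawn independently, and libraries of a group were drawn alike apart from depth. These shares therefore need not hold for real libraries that differ within a group. A simulated list of 20 members changed 2-fold had an unadjusted camera p under 0.05 in 3 of 3 simulations with either correlation. Its genes were drawn independently of each other. The simulation therefore cannot say how either setting does on members that vary together.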

Results

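Gene expression was measured by bulk RNA sequencing in 6 samples of tissue-engineered small intestine grown from human intestinal organoids, 3 with added ENCC (ENCC-HIO-TESI) and 3 without (HIO-TESI). Total counts were 40255638, 26068396 and 29560531 in ENCC-HIO-TESI replicates 2, 3 and 5. They were 31248836, 29351355 and 37859334 in HIO-TESI replicates B, D and E. Between 30712 and 33444 genes had at least 1 count in a library. Mitochondrially encoded genes took 8.88% to 11.8% of counts, and the 10 most abundant genes took 11.6% to 15.5%.

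The libraries of ENCC-HIO-TESI were not alike. Over the log2 CPM of all tested genes, the first principal component held 50.9% of the variance, and replicates 3 and 5 lay at 62.6 and 59.8 on it. Replicate 2 lay at -5.46, and HIO-TESI replicates B, D and E at -30.9, -60.7 and -25.4. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.986 between ENCC-HIO-TESI replicates 3 and 5. Replicate 2 correlated with them at 0.972 and 0.971, and with the HIO-TESI libraries at 0.981, 0.973 and 0.980.

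**Figure D1:**
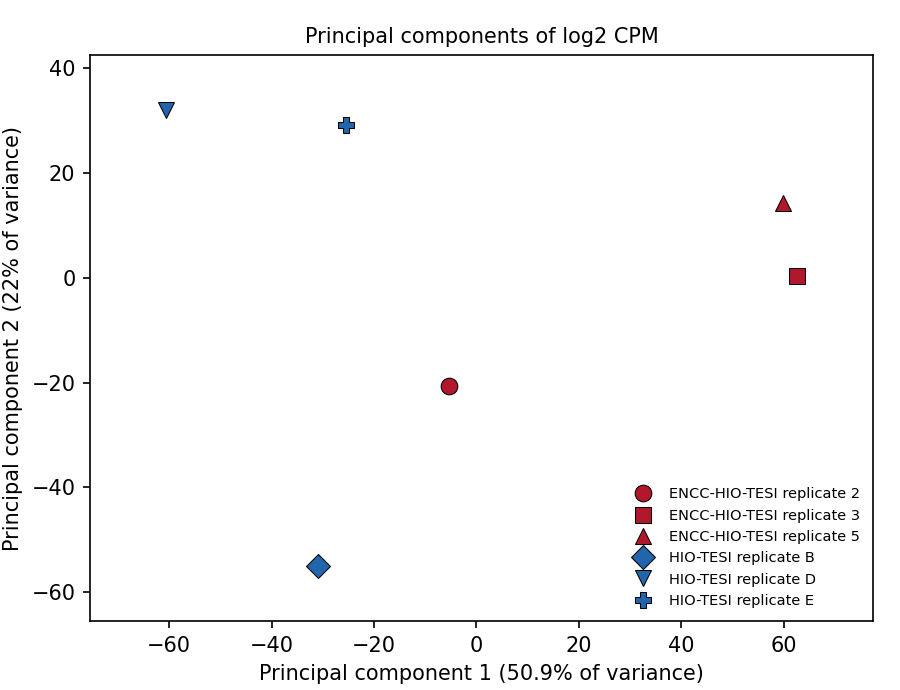
First and second principal components (50.9% and 22.0% of the variance) of log2 CPM over the tested genes, with 1 point per library and the groups in different colours. ENCC-HIO-TESI replicates 3 and 5 sit at 62.6 and 59.8 on the first component, and replicate 2 at -5.46, among positions closer to the HIO-TESI libraries.

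The comparison of ENCC-HIO-TESI with HIO-TESI asks whether cells of the added neural crest lineage are seen after 3 months of growth, and how tissue grown with them differs. Several genes of enteric neurons and glia, among them VIP, NOS1 and S100B, were higher in ENCC-HIO-TESI replicates 3 and 5 than in HIO-TESI, and were no higher in replicate 2. VIP, a peptide of inhibitory neurons, was at 4.94 CPM in replicate 3 and 3.33 CPM in replicate 5. It had 0 counts in replicate 2 and 3 counts in all over the 3 HIO-TESI libraries. NOS1, the neuronal nitric oxide synthase of inhibitory motor neurons, was at 23.6 and 18.3 CPM in replicates 3 and 5, at 0.321 CPM in replicate 2 and at 0.0699 to 0.758 CPM in HIO-TESI. In contrast, the gastric mucin MUC5AC was higher and the intestinal mucin MUC2 lower in all 3 ENCC-HIO-TESI libraries than in every HIO-TESI library: MUC5AC averaged 194.5 ± 130.2 CPM (SD, n = 3) against 7.76 ± 5.58 CPM, and MUC2 averaged 574 ± 221 CPM against 1825 ± 428 CPM.

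Most of the other fixed markers divided the same way. NOS1 is ENSG00000089250, at 117208142 to 117452170 on chromosome 12 of GRCh38. ELAVL4, a neuronal RNA-binding protein, was at 4.68 and 3.27 CPM in replicates 3 and 5 and at 0.140 to 0.220 CPM in the other 4 libraries. The glial calcium-binding protein S100B was at 5.43 and 4.34 CPM in replicates 3 and 5, and at most 0.110 CPM elsewhere. RET, the GDNF receptor of the crest lineage, was at 11.7 and 10.8 CPM in replicates 3 and 5, and at 1.65 to 2.85 CPM elsewhere. The neuronal hydrolase UCHL1 was at 22.2 and 16.3 CPM in replicates 3 and 5, and at 4.96 to 8.14 CPM elsewhere. CHAT, which makes acetylcholine, stayed low, at 0.271 to 1.04 CPM in ENCC-HIO-TESI and 0.0989 to 0.411 CPM in HIO-TESI. The neuronal tubulin TUBB3 did not exceed 0.227 CPM in any library.

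Of the 10 fixed markers in the table, 5 were tested, and 4 of them, RET, UCHL1 and NOS1 included, had an unadjusted p under 0.05. None passed the adjusted threshold in the edgeR quasi-likelihood test. The log2 fold change was 5.03 ± 1.41 (SE) for NOS1, with an adjusted p of 0.233, and 1.61 ± 0.63 (SE) for RET, with an adjusted p of 0.330. It was 1.32 ± 0.39 (SE) for UCHL1 and 1.53 ± 0.65 (SE) for CHAT, with adjusted p of 0.243 and 0.356. Without ENCC-HIO-TESI replicate 2, 7 of 9 tested markers passed, all higher, among them VIP, ELAVL4, NOS1, UCHL1, S100B and RET. Leaving out any other library gave 0. DESeq2 called 4 markers with all 6 libraries, among them ELAVL4, NOS1 and UCHL1. In the authors' deposited table, VIP has an adjusted p of 3.8e-07, and NOS1 a log2 fold change of 3.99 (0.00664).

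**Figure D2:**
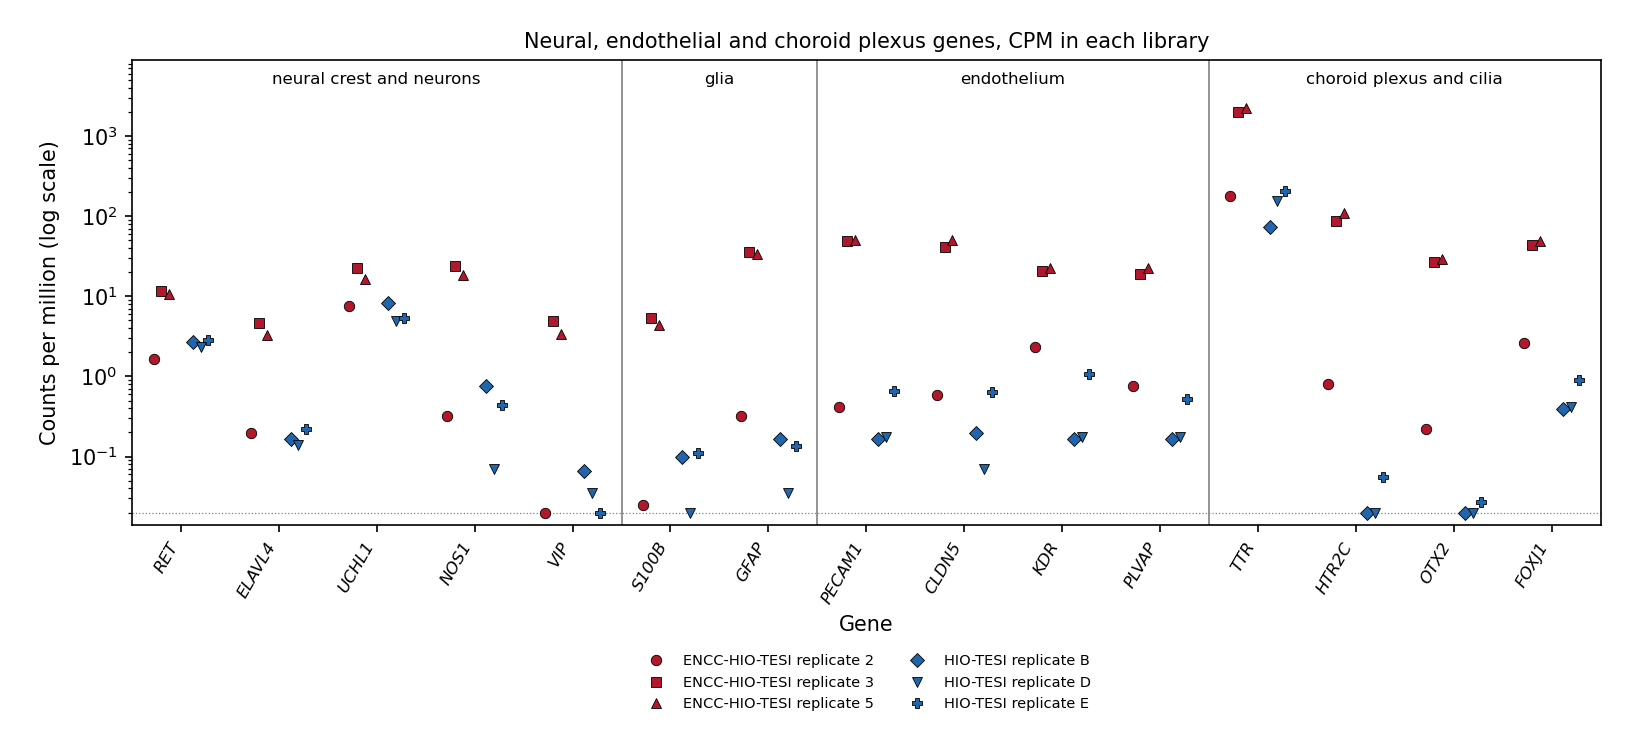
CPM on a log axis of neuronal, glial, endothelial and choroid plexus or cilia genes, with 1 point per library and colours for the groups; values under 0.02 CPM, 0 included, are drawn at 0.02 (dotted line). NOS1 reaches 23.6 and 18.3 CPM in ENCC-HIO-TESI replicates 3 and 5 and stays at or under 0.758 CPM in the other 4 libraries.

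Over all 20372 tested genes, the edgeR quasi-likelihood test called 0 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.199. At an unadjusted p under 0.05 it gave 2881 genes, 1770 higher and 1111 lower in ENCC-HIO-TESI. The share higher was 61.4%, and 59.3% with RLE, 68.5% with upper-quartile and 81.9% with total-count scaling. Limma-voom also called 0 genes, with 2577 at an unadjusted p under 0.05. DESeq2 called 850 genes, 677 higher and 173 lower. The authors' deposited table holds 849 genes at an adjusted p under 0.05, 676 higher and 173 lower, of which 590 are also among the DESeq2 calls. Of the 676 higher genes of the authors' deposited table, replicate 2 was above every HIO-TESI library in 471, and replicates 3 and 5 in 674 each. These genes were selected as higher in the same libraries, so these counts describe the selection and test nothing. A trace is enough to be above: SLC22A8 had 4 counts in replicate 2, beside 223 and 313 in replicates 3 and 5. The groups did not overlap in 3925 tested genes, 19.3%, where chance gives 10% on average for 3 libraries against 3, and other splits of the same libraries gave up to 3374. One library decided the count: without ENCC-HIO-TESI replicate 2 the quasi-likelihood test called 737 genes, 674 higher and 63 lower. Without replicate 3 it called 1 gene, the prostate stem cell antigen PSCA, and without replicate 5 it called 1 gene, lysozyme (LYZ). Without any of the HIO-TESI libraries it called 0.

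Among the genes with the smallest p in the quasi-likelihood test, chosen after their values were seen, the groups differed by more than the spread between replicates while the adjusted p stayed at 0.199. CLDN1, a tight junction claudin, was at 45.4 ± 4.62 CPM (SD, n = 3) against 15.8 ± 3.02 CPM, a log2 fold change of 1.52 ± 0.16 (SE). The lipid transporter ABCA7 had a log2 fold change of 1.49 ± 0.20 (SE). STRA6, a receptor for retinol-binding protein, had one of 2.05 ± 0.30 (SE). BRINP3 was lower, by -1.28 ± 0.17 (SE), and CNTN5, a neuronal adhesion protein, by -1.61 ± 0.24 (SE).

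The rule for the largest changes, applied to the authors' calls, named 10 higher and 10 lower genes. The iodide transporter SLC5A5, with an adjusted p of 9.6e-24 in the authors' deposited table, was at 37.7 and 47.5 CPM in replicates 3 and 5, at 0.321 CPM in replicate 2, and at 0 counts in every HIO-TESI library. The serotonin receptor HTR2C, the solute carriers SLC22A8 and SLC39A12, the transcription factors ZIC4, ZIC5 and OTX2, and MFRP had the same distribution. HTR2C was at 86.5 and 109.6 CPM in replicates 3 and 5 and at 0.814 CPM in replicate 2, and had 2 counts in all over HIO-TESI. Trypsinogen PRSS1 and the elastase CELA3A were the other 2 higher genes, and counts of both are uncertain, because these genes have near-identical copies and how reads were divided between copies is not known. The 10 lower genes were NXPE4, IL1R2, CEACAM7, HAVCR1, NEU4, ZG16, DHRS9, MT1H, NXPE1 and HOXC10. In the quasi-likelihood test their log2 fold changes ran from -5.57 ± 1.36 (SE) for NXPE4 to -2.15 ± 0.71 (SE) for HOXC10, and IL1R2, a decoy receptor for interleukin 1, was at -4.22 ± 0.73 (SE).

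As sets, 12 of 32 lists were called by camera with its preset correlation, 7 higher and 5 lower in ENCC-HIO-TESI. The balance of directions depended on the setting: 5 higher and 6 lower with upper-quartile scaling, 4 and 9 with total counts, and 5 and 8 with 1 unwanted factor. With an estimated correlation 0 were called, at a smallest adjusted p of 0.278, so each set result below is given with both adjusted p-values. Over all genes tested, 0 list members passed, and 62 passed when adjusted over the list alone, 45 higher and 17 lower. Without ENCC-HIO-TESI replicate 2, 61 members passed over all genes, 54 higher and 7 lower, and without replicate 5, 1 passed.

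Pan-neuronal genes were higher as a set, with all 17 tested members on that side and a median log2 fold change of 1.26 (adjusted p 3.23e-05, and 0.586 with an estimated correlation). Adjusted over the list alone, 4 passed: DCX, a microtubule protein of young neurons, UCHL1, STMN2 and the synaptic SNAP25. DCX was at 5.50, 18.8 and 15.3 CPM in ENCC-HIO-TESI and at 3.86 to 4.61 CPM in HIO-TESI, a log2 fold change of 1.65 ± 0.42 (SE). STMN2 had a log2 fold change of 1.63 ± 0.41 (SE) and SNAP25 one of 0.77 ± 0.22 (SE). At least 2-fold above every HIO-TESI library were 0 members in replicate 2, 10 in replicate 3 and 6 in replicate 5.

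Enteric neuron subtype genes were also higher, 10 of 13 members, with a median log2 fold change of 0.74 (adjusted p 0.0195, and 0.586 with an estimated correlation). The call was lost with total-count scaling (0.0670). NOS1, PENK, ADCYAP1 and GAD2 passed adjusted over the list alone. PENK, the enkephalin precursor, was highest in replicate 2, at 5.65 CPM, against 2.83 and 2.95 CPM in replicates 3 and 5 and 0.428 to 1.62 CPM in HIO-TESI, a log2 fold change of 1.77 ± 0.50 (SE). The peptide ADCYAP1 had a log2 fold change of 1.60 ± 0.49 (SE), and GAD2, which makes GABA, one of 1.01 ± 0.23 (SE).

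Enteric neural crest genes were not called as a set (9 of 14 members higher, median 0.20, adjusted p 0.197, and 0.832 with an estimated correlation). They were called without ENCC-HIO-TESI replicate 2 (6.94e-05), HIO-TESI replicate B (0.0201) or HIO-TESI replicate E (0.0122). NGFR, the low-affinity nerve growth factor receptor, and the transcription factor HAND2 passed adjusted over the list alone, and both were higher in all 3 libraries. NGFR was at 38.8 ± 5.18 CPM (SD, n = 3) against 20.3 ± 5.64 CPM, a log2 fold change of 0.93 ± 0.22 (SE), and HAND2 had a log2 fold change of 0.58 ± 0.12 (SE).

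Glia and Schwann cell genes were not called (9 of 12 higher, median 0.32, adjusted p 0.212, and 0.609 with an estimated correlation). They were called without ENCC-HIO-TESI replicate 2 (9.06e-06), HIO-TESI replicate D (0.0262) or HIO-TESI replicate E (0.0215). L1CAM, an adhesion protein of crest cells and axons, passed adjusted over the list alone, at 0.765, 21.0 and 12.1 CPM against at most 0.521 CPM in HIO-TESI. GFAP, chosen after its values were seen, was at 35.5 and 33.5 CPM in replicates 3 and 5 and at 0.0350 to 0.321 CPM elsewhere. The myelin gene MBP had a log2 fold change of -0.27 ± 0.10 (SE).

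Signals to the enteric nervous system were not shifted as a set. Of 19 members, 9 were higher and 10 lower, with a median of -0.01 and a mean of 0.24, and the set test pointed lower (adjusted p 0.876, and 0.945 with an estimated correlation). IHH, the hedgehog ligand of intestinal epithelium, had a log2 fold change of -0.52 ± 0.15 (SE), while SHH, a foregut and crypt hedgehog ligand, had one of 0.86 ± 0.37 (SE). The axon repellent SEMA3A had one of -0.45 ± 0.19 (SE).

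Stomach and foregut genes were higher in every ENCC-HIO-TESI library, replicate 2 included. All 11 tested members were higher and did not overlap between groups, the median log2 fold change was 4.26, and all 11 passed adjusted over the list alone (set adjusted p 2.15e-08, and 0.278 with an estimated correlation). DESeq2 called 9 of them. MUC5AC (ENSG00000215182, chromosome 11, 1157953 to 1201138) was at 326, 193 and 65.2 CPM in ENCC-HIO-TESI and at 8.07, 2.03 and 13.2 CPM in HIO-TESI, a log2 fold change of 4.64 ± 0.81 (SE). The trefoil peptide TFF2 was at 31.3, 130.4 and 5.76 CPM in ENCC-HIO-TESI and at 0.874 to 1.98 CPM in HIO-TESI. The gastric claudin CLDN18 had a log2 fold change of 2.55 ± 0.58 (SE), and gastrin (GAST) one of 4.51 ± 0.90 (SE). PDX1, a transcription factor of antrum, duodenum and pancreas, averaged 30.9 ± 8.35 CPM (SD, n = 3) against 17.3 ± 1.10 CPM. At least 2-fold above every HIO-TESI library were 9, 9 and 8 members in replicates 2, 3 and 5. Leaving out single libraries, the set kept an adjusted p between 1.79e-11 and 1.17e-06.

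Goblet cell genes had lower fitted values in ENCC-HIO-TESI, all 13 members, though the groups overlapped in 7 of them, with a median log2 fold change of -1.27 (adjusted p 1.3e-07, and 0.586 with an estimated correlation). MUC2 (ENSG00000198788, chromosome 11, 1074875 to 1110511) was at 486, 410 and 825 CPM in ENCC-HIO-TESI and at 1661, 2311 and 1504 CPM in HIO-TESI, a log2 fold change of -1.67 ± 0.31 (SE). The goblet cell lectin ZG16 had one of -3.68 ± 0.70 (SE) and SPINK4 one of -2.42 ± 0.52 (SE). GALNT12, which glycosylates mucins, had one of -0.88 ± 0.23 (SE). These 4 genes, TFF3 and FCGBP passed adjusted over the list alone. DESeq2 called the same 6.

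Colon genes had lower fitted values in ENCC-HIO-TESI, all 8 tested members, with a median of -1.46 (adjusted p 4.31e-05, and 0.437 with an estimated correlation). The groups did not overlap in 4 of the 11 members in the table. Among members at 1 CPM or more in every HIO-TESI library, 1 in replicate 2 was at least 2-fold below all of these libraries. In replicates 3 and 5 the numbers were 4 and 3. Adjusted over the list alone, 6 members passed, among them CEACAM7, HOXB13, AQP8, CA4 and SLC26A2. CEACAM7, an adhesion protein of colonic surface cells, was at 3.33, 4.65 and 0.745 CPM in ENCC-HIO-TESI and at 22.6, 64.4 and 27.0 CPM in HIO-TESI, a log2 fold change of -3.71 ± 0.67 (SE). The carbonic anhydrase CA4 had one of -1.59 ± 0.41 (SE) and the water channel AQP8 one of -1.07 ± 0.25 (SE). HOXB13, a hindgut factor, was at 19.5 CPM in HIO-TESI replicate D, 4.25 CPM in replicate E and 0.461 CPM in replicate B, so the HIO-TESI libraries also differed among themselves.

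HOX genes were not called as a set (12 higher and 17 lower of 29, median -0.08, adjusted p 0.212, and 0.895 with an estimated correlation), but were called without ENCC-HIO-TESI replicate 2 (0.00647) or HIO-TESI replicate D (0.00367). They were also called with total-count scaling (0.0491). HOXA13, chosen after its values were seen, was at 0.186 and 0.0647 CPM in replicates 3 and 5, at 11.2 CPM in replicate 2 and at 6.04 to 15.5 CPM in HIO-TESI. HOXC10 had a log2 fold change of -2.15 ± 0.71 (SE), HOXD1 one of -1.81 ± 0.40 (SE) and HOXA9 one of -1.23 ± 0.55 (SE), while the anterior HOXA2 had one of 0.69 ± 0.32 (SE).

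**Figure D3:**
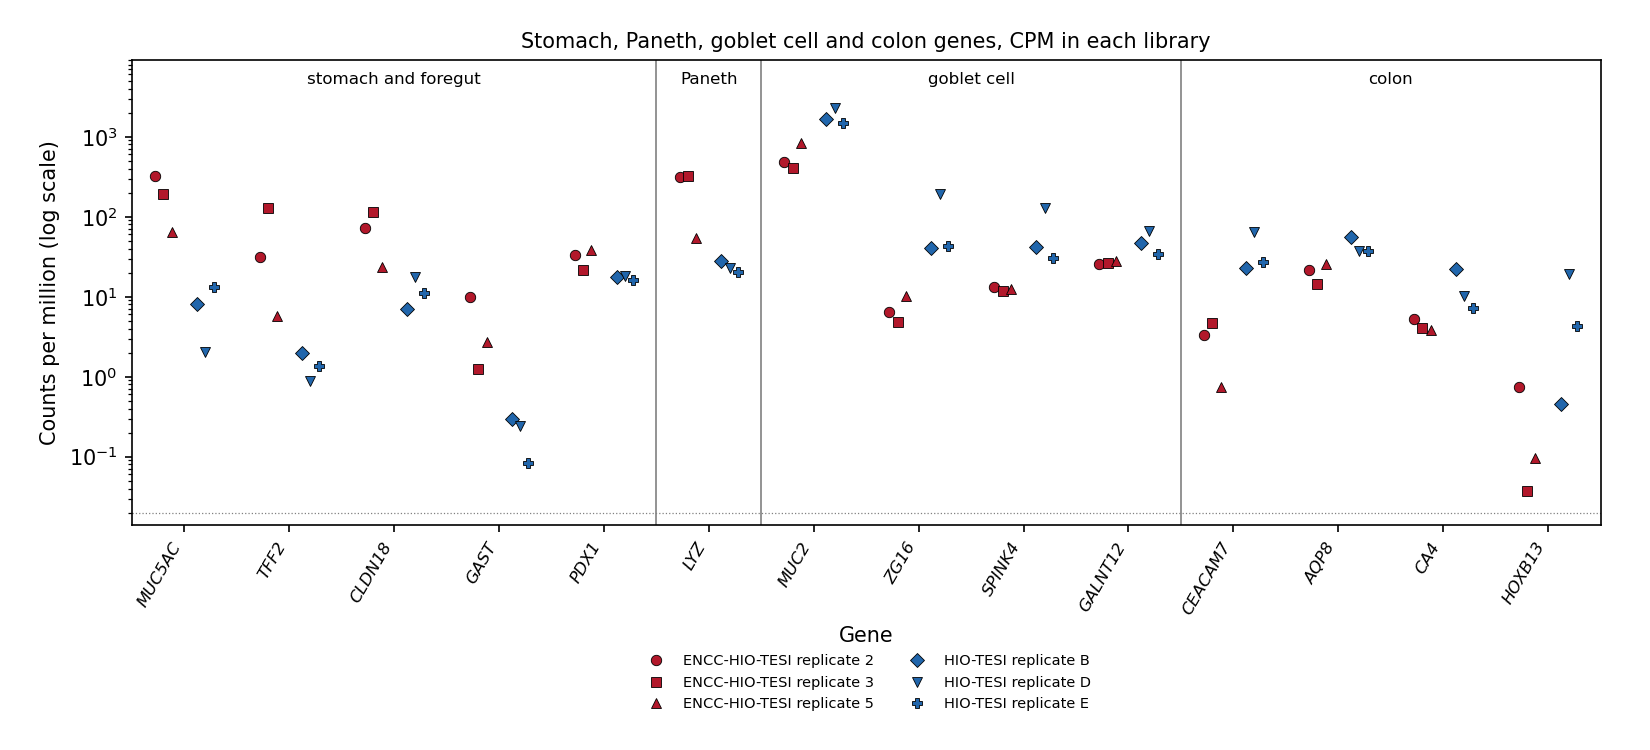
CPM on a log axis of stomach, Paneth, goblet cell and colon genes, with 1 point per library and colours for the groups; values under 0.02 CPM, 0 included, are drawn at 0.02 (dotted line). MUC5AC is between 65.2 and 326 CPM in ENCC-HIO-TESI and between 2.03 and 13.2 CPM in HIO-TESI.

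Paneth cell genes were not called (8 of 9 higher, median 1.05, adjusted p 0.125, and 0.738 with an estimated correlation), but were called without ENCC-HIO-TESI replicate 2 (0.00634) or HIO-TESI replicate D (0.0389). The antibacterial LYZ passed adjusted over the list alone, at 314, 319 and 53.7 CPM against 28.1, 22.6 and 20.6 CPM, a log2 fold change of 3.27 ± 0.63 (SE). REG3A had one of 1.49 ± 0.93 (SE) and MMP7 one of 1.79 ± 1.16 (SE). PRSS2, whose counts are uncertain for the same reason as those of PRSS1, had one of 3.82 ± 1.33 (SE).

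Pan-epithelial intestinal genes were lower as a set, 16 of 17 members, but by a median of -0.44 (adjusted p 1.58e-05, and 0.609 with an estimated correlation). The differentiation keratin KRT20 had a log2 fold change of -1.30 ± 0.31 (SE) and the antigen GPA33 one of -0.83 ± 0.21 (SE), and both passed adjusted over the list alone. KRT18 and the cadherin CDH17 were at -0.52 ± 0.16 (SE) and -0.55 ± 0.17 (SE). Proliferation genes all had lower fitted values, 16 of 16, by a median of -0.22 (adjusted p 0.000863, and 0.738 with an estimated correlation). The groups did not overlap in only 3 of the 16, and 0 passed adjusted over the list alone. The replication helicases MCM5 and MCM2 had a log2 fold change of -0.27 ± 0.09 (SE) and -0.27 ± 0.10 (SE). CCNA2 was at -0.32 ± 0.15 (SE) and PLK1 at -0.33 ± 0.16 (SE).

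Enterocyte genes varied within HIO-TESI more than between groups: 20 of 21 were lower, with a median of -0.53, and the set was not called (adjusted p 0.185, and 0.895 with an estimated correlation). It was called without HIO-TESI replicate B (3.82e-07) or ENCC-HIO-TESI replicate 5 (0.0232), with total-count scaling (0.0356) and with 1 unwanted factor (0.0262). The peptidases DPP4 and ANPEP had log2 fold changes of -0.60 ± 0.21 (SE) and -0.57 ± 0.28 (SE), the fatty acid carrier FABP1 one of -0.46 ± 0.30 (SE) and APOA1 one of -0.99 ± 0.67 (SE). Brush border digestion and lipid transport genes behaved alike (16 of 20 lower, median -0.22, adjusted p 0.0560, and 0.738 with an estimated correlation), and were called without HIO-TESI replicate B (7.66e-05) or ENCC-HIO-TESI replicate 5 (0.0121), with upper-quartile (0.0412) or total-count scaling (0.0154), and with 1 unwanted factor (0.0170). GUCA2A, which encodes guanylin, passed adjusted over the list alone, at -1.31 ± 0.24 (SE). The sodium exchanger SLC9A3 had a log2 fold change of -0.68 ± 0.21 (SE), the iron exporter SLC40A1 one of -0.40 ± 0.14 (SE) and GUCA2B one of -1.27 ± 0.57 (SE).

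Enteroendocrine genes were not called (9 higher and 11 lower of 20, median -0.06, adjusted p 0.751, and 0.945 with an estimated correlation). Glucagon (GCG) was at 108.5 ± 33.7 CPM (SD, n = 3) against 240.7 ± 47.6 CPM, a log2 fold change of -1.15 ± 0.26 (SE). Neurotensin (NTS) was lower, at -1.71 ± 0.62 (SE), and ghrelin (GHRL) and PAX4 higher, at 1.22 ± 0.49 (SE) and 0.99 ± 0.41 (SE). Intestinal stem cell genes were not called either (6 higher and 8 lower of 14, median -0.20, adjusted p 0.517, and 0.895 with an estimated correlation). RGMB, EPHB2 and CDCA7 had log2 fold changes of -0.56 ± 0.13 (SE), -0.42 ± 0.21 (SE) and -0.41 ± 0.20 (SE), and SOX9 one of 0.58 ± 0.24 (SE).

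Smooth muscle genes were lower as a set, 17 of 18, by a median of -0.24 (adjusted p 0.00600, and 0.749 with an estimated correlation). The groups overlapped in all 18 members, and replicate 2, with a mean log2 CPM of 9.55 over the list, lay within the HIO-TESI range of 9.30 to 9.64, while replicates 3 and 5 lay at 9.08 and 8.90. The call was lost without ENCC-HIO-TESI replicate 5 (0.161) or HIO-TESI replicate B (0.176). The enteric actin ACTG2 had a log2 fold change of -0.61 ± 0.25 (SE). TAGLN, ACTA2 and CNN1 were at -0.58 ± 0.26 (SE), -0.51 ± 0.25 (SE) and -0.58 ± 0.30 (SE). Genes of interstitial cells of Cajal and PDGFRA cells were not shifted (5 higher and 5 lower, median 0.06, adjusted p 0.927, and 0.960 with an estimated correlation). Their gap junction gene GJA1 had a log2 fold change of 1.02 ± 0.35 (SE), ETV1 one of 0.17 ± 0.13 (SE), P2RY1 one of -0.38 ± 0.17 (SE) and THBS4 one of -0.77 ± 0.46 (SE). Fibroblast and matrix genes had a median of 0.05 (11 of 16 higher, adjusted p 0.619, and 0.945 with an estimated correlation), but were called lower without HIO-TESI replicate D (0.00193), in which collagens were low. POSTN, DCN, MFAP4 and THY1 had log2 fold changes of 0.21 ± 0.12 (SE), -0.24 ± 0.17 (SE), -0.21 ± 0.20 (SE) and 0.21 ± 0.22 (SE).

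Cartilage and bone genes had higher fitted values, all 16 tested members, by a median of 0.99 (adjusted p 3.06e-05, and 0.437 with an estimated correlation). The groups did not overlap in 7 of the 19 members in the table. COL9A2, COMP, COL11A2, COL9A3 and MATN4 passed adjusted over the list alone. COMP, a cartilage matrix protein, was at 51.0, 42.2 and 20.7 CPM against 12.3, 5.10 and 3.95 CPM, a log2 fold change of 2.42 ± 0.50 (SE). The fibrillar collagen COL11A2 had one of 1.79 ± 0.37 (SE), COL9A2 one of 2.21 ± 0.53 (SE) and the matrilin MATN4 one of 1.93 ± 0.51 (SE). Melanocyte genes were not called (4 of 5 higher, median 0.79, adjusted p 0.268, and 0.738 with an estimated correlation). TYRP1, a pigment enzyme, passed adjusted over the list alone, at 2.83 ± 0.81 (SE), with MITF at 0.92 ± 0.32 (SE), OCA2 at 0.79 ± 0.59 (SE) and PMEL at -0.29 ± 0.24 (SE).

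Endothelial genes were higher as a set, all 12, by a median of 4.77 (adjusted p 5.87e-05, and 0.626 with an estimated correlation), and most of the difference lay in replicates 3 and 5. At least 2-fold above every HIO-TESI library were 1 member in replicate 2, and 8 in each of replicates 3 and 5. KDR, the VEGF receptor of endothelium, was at 20.9 and 22.8 CPM in replicates 3 and 5, at 2.32 CPM in replicate 2 and at 0.165 to 1.07 CPM in HIO-TESI. Its log2 fold change was 4.95 ± 1.05 (SE), and PLVAP, CLDN5 and CDH5 had 5.55 ± 1.24 (SE), 6.57 ± 1.56 (SE) and 6.18 ± 1.51 (SE). These 4 genes with PECAM1, VWF, TIE1 and ESAM passed adjusted over the list alone.

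Only 3 of 19 blood and immune genes in the table were tested, 1 higher and 2 lower, with a median of -0.28. LAPTM5, CSF1R and AIF1 had log2 fold changes of -0.46 ± 0.32 (SE), -0.28 ± 0.56 (SE) and 0.06 ± 0.50 (SE). The leukocyte phosphatase PTPRC, chosen after its values were seen, was at 7.96 and 7.06 CPM in replicates 3 and 5 and at most 0.222 CPM elsewhere, while the myeloid genes TYROBP, C1QA and C1QB had 0 counts in all 6 libraries. Adipocyte and mesothelium genes were called higher (7 of 10, median 0.53, adjusted p 0.0437, and 0.738 with an estimated correlation), a call lost without ENCC-HIO-TESI replicate 2 (0.0603) or 3 (0.108) or HIO-TESI replicate B (0.176) or D (0.214). It was also lost with upper-quartile (0.0647) or total-count scaling (0.12) and with 1 unwanted factor (0.0632). The mesothelial factor WT1 had a log2 fold change of 1.20 ± 0.40 (SE), UPK3B one of 1.39 ± 0.52 (SE), and the adipocyte genes FABP4 and PLIN1 had 1.89 ± 0.74 (SE) and 0.81 ± 0.34 (SE).

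Liver and pancreas genes were called higher (8 of 10, median 0.70, mean 3.10, adjusted p 0.0382, and 0.586 with an estimated correlation), a call lost without HIO-TESI replicate B (0.450), with upper-quartile (0.05) or total-count scaling (0.0942), and with 1 unwanted factor (0.0616). ALB, PRSS1, CELA3A and CPA1 passed adjusted over the list alone. Albumin (ALB) was at 14.2, 131 and 10.5 CPM against 0.734 to 2.47 CPM in HIO-TESI. The pancreatic carboxypeptidase CPA1 was at 207 CPM in replicate 5, 15.1 CPM in replicate 3 and 0.666 CPM in replicate 2, against 0.428 to 0.804 CPM.

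Of the central nervous system genes 3 of 16 were tested, all higher, and TTR and PAX6 passed adjusted over the list alone. Transthyretin (TTR) was at 1985 and 2251 CPM in replicates 3 and 5, at 178 CPM in replicate 2 and at 72.7 to 205 CPM in HIO-TESI, a log2 fold change of 3.35 ± 0.88 (SE). PAX6 had one of 1.24 ± 0.35 (SE) and EMX2 one of 2.29 ± 1.12 (SE). Lung and thyroid genes gave 3 tested members, 2 higher, with FOXJ1, the regulator of motile cilia, passing adjusted over the list alone at 5.76 ± 1.11 (SE); PAX8 was at -0.70 ± 0.36 (SE) and TG at 0.54 ± 0.31 (SE). Of the pluripotency genes 3 of 10 were tested, with a median of 0.08 and a mean of the other sign, -0.25, and L1TD1 passed adjusted over the list alone, at -0.95 ± 0.29 (SE), beside DNMT3B at 0.08 ± 0.17 (SE) and DPPA4 at 0.11 ± 0.84 (SE).

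Kidney genes were not called (3 of 5 higher, median 1, mean 0.55, adjusted p 0.674, and 0.895 with an estimated correlation), with EYA1 at 2.47 ± 0.79 (SE) and CDH16 at -1.20 ± 0.49 (SE). Heart muscle genes were not called (3 of 5 higher, median 0.08, mean -0.04, set direction higher, adjusted p 0.927, and 0.960 with an estimated correlation), except without ENCC-HIO-TESI replicate 3 (0.0164). MYH7 passed adjusted over the list alone, at 0.84 ± 0.22 (SE), with HAND1 at -0.28 ± 0.11 (SE), ACTC1 at -1.21 ± 0.98 (SE) and TNNT2 at 0.36 ± 0.43 (SE). Skeletal muscle genes were not called (6 of 10 higher, median 0.21, adjusted p 0.622, and 0.895 with an estimated correlation), with TNNI2 at 1.20 ± 0.56 (SE), ACTA1 at -0.78 ± 0.46 (SE), TNNC2 at -0.81 ± 0.55 (SE) and CHRNA1 at 0.62 ± 0.47 (SE). Of the skin and squamous genes 3 of 10 were tested, all lower, by a median of -2.49, with KRT10 at -0.62 ± 0.22 (SE). KRT13 and KRT5 were at -4.57 ± 1.85 (SE) and -2.49 ± 1.80 (SE), and both changed sign without HIO-TESI replicate E (0.56 and 5.84).

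Stress and immediate early genes were not called (10 of 15 lower, median -0.09, adjusted p 0.162, and 0.832 with an estimated correlation), except without HIO-TESI replicate B (0.00527). The heat shock genes HSPA1B and DNAJB1 had log2 fold changes of -0.93 ± 0.25 (SE) and -0.70 ± 0.21 (SE), ATF3 one of -0.61 ± 0.24 (SE) and JUNB one of -0.44 ± 0.19 (SE). Hypoxia genes were not called (11 of 13 lower, median -0.22, adjusted p 0.0560, and 0.586 with an estimated correlation), but were called without ENCC-HIO-TESI replicate 3 (0.0255) or HIO-TESI replicate B (0.00527), with total-count scaling (0.0424) and with 1 unwanted factor (0.0238). PDK1, which turns pyruvate from mitochondria, passed adjusted over the list alone, at -0.62 ± 0.14 (SE). The hexokinase HK2 was at -1.32 ± 0.38 (SE), EGLN3 at -0.29 ± 0.12 (SE) and CA9 at 1.11 ± 0.51 (SE).

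Interferon response genes were not called (5 of 14 higher, median -0.04, mean 0.03, set direction lower, adjusted p 0.310, and 0.895 with an estimated correlation), except without ENCC-HIO-TESI replicate 3 (0.0115). OAS1, MX1 and ISG15 were at -0.43 ± 0.19 (SE), -0.40 ± 0.25 (SE) and -0.35 ± 0.21 (SE), and IFI44L at 0.98 ± 0.70 (SE). Inflammation genes were not called (4 of 9 higher, median -0.05, mean -0.21, while the set test pointed higher, adjusted p 0.927, and 0.960 with an estimated correlation). CCL2 was at 0.77 ± 0.36 (SE), CCL20 at -1.17 ± 0.83 (SE) and DUOX2 at -1.08 ± 0.84 (SE), while CXCL2 averaged 0.389 ± 0.203 CPM (SD, n = 3) against 0.798 ± 0.466 CPM. Mitochondrially encoded genes were not called (4 of 13 higher, median -0.05, adjusted p 0.343, and 0.895 with an estimated correlation), except without ENCC-HIO-TESI replicate 3 (0.000378). MT-CO1, MT-CO3, MT-ND3 and MT-CO2 were at -0.15 ± 0.24 (SE), -0.12 ± 0.20 (SE), -0.13 ± 0.22 (SE) and -0.09 ± 0.20 (SE).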

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

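Of the alternatives below, the likelihood ratio test, the newer deviances, the filter of 10 counts in 2 libraries and the 2 combinations without ENCC-HIO-TESI replicate 2 were chosen only after the data were seen. The edgeR quasi-likelihood test called 0 genes. It called 404 with no filter (341 higher, 63 lower), 2 with 1 unwanted factor as a covariate (CELA3A and PGC), and between 0 and 737 with single libraries left out, the highest without ENCC-HIO-TESI replicate 2. DESeq2 called 850 genes and the likelihood ratio test 638 (510 higher, 128 lower), and in simulated data 26.5% and 24.3% of the calls of these 2 tests were unchanged genes. The simulation drew genes independently and held no library that departs from its group. It held the 20372 filtered genes, while DESeq2 tested 40665 genes of the real counts. The simulated shares therefore cannot be read as the unchanged share of the 850 and 638 calls. Without replicate 2, the quasi-likelihood test with no filter called 1618 and the likelihood ratio test 1572. Of the 737 genes, 494 are among the authors' calls and 490 among those of DESeq2. The count stayed at 0 with RLE, upper-quartile or total-count scaling, the stricter filter, protein-coding genes only, voom, the newer deviances, the filter of 10 counts in 2 libraries, and the stricter thresholds. The 12 lists called by camera became 0 with an estimated correlation and 1 with fry, the stomach list, at an adjusted p of 0.0482. The number called was 12 with RLE, 11 with upper-quartile scaling (2 of the 12 lost, 1 gained), 13 with total counts (3 lost, 4 gained), 13 with the unwanted factor (2 lost, 3 gained), and 13 to 16 with single libraries left out (0 to 3 lost). With single libraries left out, the fibroblast and matrix list ranged from an adjusted p of 0.00193, pointing lower, without HIO-TESI replicate D to 0.782 without ENCC-HIO-TESI replicate 2; it was at 0.945 with an estimated correlation and 0.844 with fry. Of list members, 2 passed with the unwanted factor, 62 adjusted over the list alone, and between 0 and 61 with single libraries left out, the highest without ENCC-HIO-TESI replicate 2. Of the neural crest, neuronal and glial markers, 0 passed in the quasi-likelihood test, 2 with no filter (ELAVL4 and NOS1), 4 with DESeq2, 1 with the likelihood ratio test (NOS1), and 0 to 7 with single libraries left out. Without replicate 2, 8 passed with no filter and 9 with the likelihood ratio test. The 193 tested genes followed one by one kept their direction with RLE, upper-quartile and total-count scaling, while 2 changed direction with the unwanted factor, 5 with voom and 1 to 6 with single libraries left out. Alternatives for normalized values, the pseudocount and a filter on low values, were not run because the table holds counts.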

Other observations

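All tests in this part were chosen only after the results were seen, except that of scaling and the splits of the samples. ENCC-HIO-TESI replicates 3 and 5 carried genes of choroid plexus, the brain tissue that makes cerebrospinal fluid. The sulfate transporter SLC13A4 was at 109.7 and 123.6 CPM in them, at 2.34 CPM in replicate 2 and at 1.29 to 1.59 CPM in HIO-TESI. The folate receptor FOLR1 was at 49.6 and 55.2 CPM against 2.66 CPM in replicate 2, and the channel TRPM3 at 44.7 and 52.4 CPM against 0.814 CPM. OTX2, which specifies this tissue, was at 27.1 and 29.4 CPM, at 0.222 CPM in replicate 2 and at 1 count in all over HIO-TESI. Of 16 choroid plexus genes, 8 were at least 4-fold above every HIO-TESI library in each of replicates 3 and 5, and 0 in replicate 2; 2 of the 16, TTR and OTX2, are also in the central nervous system list, and 11 reached 1 CPM in each HIO-TESI library. Genes of motile cilia went with them, 14 of 20 in each of replicates 3 and 5 and 0 in replicate 2. The dynein DNAH9 was at 21.3 and 22.7 CPM and HYDIN at 18.5 and 19.1 CPM, against at most 1.46 CPM elsewhere. FOXJ1 is also in the lung and thyroid list, and 5 or 6 of the 20 reached 1 CPM in the HIO-TESI libraries. These lists were written after the genes were seen, so the counts describe and do not test. In the fixed neural lists, the same count in replicates 3 and 5 was 5 and 0 of 20 pan-neuronal genes, 2 and 0 of 19 enteric neural crest genes, 3 and 2 of 22 enteric neuron subtype genes and 3 and 3 of 19 glia and Schwann cell genes.

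Pancreatic acinar genes were high in replicate 5 and lower in replicate 3, with 9 and 6 of 13 members at least 4-fold above every HIO-TESI library and 0 in replicate 2. This list too was written after the data were seen, and several members are near-identical copies (PRSS1, CELA3A, CELA3B, CTRB1, CTRB2) whose counts are uncertain. Of the 13, 6 are in the liver and pancreas list, and 3 reached 1 CPM in each HIO-TESI library. The lipase CEL was at 1818 CPM in replicate 5 and at 194 to 289 CPM in the other 5 libraries. Single HIO-TESI libraries stood apart as well. HIO-TESI replicate E carried squamous keratins, with KRT13 at 46.9 CPM, KRT5 at 36.6 CPM and KRT4 at 29.3 CPM, where the other 5 libraries had at most 1.23, 2.34 and 3.23 CPM. HIO-TESI replicate B was low in enterocyte genes: the apolipoprotein APOA4 was at 30.8 CPM against 793 and 2008 CPM in replicates D and E, and the retinol carrier RBP2 at 34.8 CPM against 735 and 596 CPM. The colonic hormone INSL5 was seen in HIO-TESI replicates D and E, at 2.94 and 1.04 CPM, and had 0 counts in the other 4 libraries.

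Many neuronal, choroid plexus-type and endothelial genes were much higher in ENCC-HIO-TESI replicates 3 and 5 than in replicate 2, although PENK was highest in replicate 2 and KDR was above HIO-TESI there, at 2.32 CPM. That replicate 2 is a mislabelled library like the 3 HIO-TESI libraries is argued against by the stomach genes: 9 of 14 were at least 2-fold above every HIO-TESI library in replicate 2, while at most 1 stood as far above the other HIO-TESI libraries in any HIO-TESI library. HOXA13, at 11.2 CPM, and the correlations of replicate 2 (0.981, 0.973 and 0.980 with HIO-TESI) go the other way, so an HIO-TESI library of another preparation stays open. Cells of choroid plexus type (8 members in each of replicates 3 and 5) and cells of retinal pigment epithelium type (1 of 12 members in each) may each be a source of part of the pattern, and these counts decide neither. Of the retinal pigment epithelium genes, 4 are in the melanocyte list and 6 reached 1 CPM in each HIO-TESI library, and RLBP1, RGR and TYRP1 are among the higher calls of the authors' deposited table. Also open are reads from host mouse blood, since haemoglobin genes summed to at most 0.037 CPM in replicates 3 and 5 beside PECAM1 at 48.6 CPM in replicate 3 but how many mouse reads count on a human gene is not known, a difference in organoid preparation, and the added ENCC, which were unsorted.

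Stomach genes were higher and goblet cell genes lower in ENCC-HIO-TESI. A lower epithelial share could explain part of the goblet cell difference and stays open: relative to pan-epithelial genes, goblet cell genes differed by -0.85 in mean log2 CPM, with a gap of 0.15 between the nearest libraries of the groups and an SD of up to 0.50 within a group. Scaling of the libraries is argued against: over 4 scalings the goblet cell median was at most -1.18 and the stomach median at least 4.25. Total-count scaling moved the median of all genes to 0.079. An organoid batch that differed between the groups cannot be told apart from the added ENCC, since the labels give no batch.

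Many genes were called without ENCC-HIO-TESI replicate 2. That any library left out frees calls is argued against, since leaving out each of the other 5 gave at most 1 gene against 737. A candidate explanation is that replicate 2 held few descendants of the added cells, which was not tested. The 6 libraries make 10 splits into 3 and 3, so the share of splits is never under 0.1. In the quasi-likelihood test all 10 gave as many genes as the real count of 0, and the highest other was 1. With DESeq2 only 1 split, the real one, gave 850 genes, and the highest other was 578. With camera, 2 splits gave at least the 12 lists of the real one, and the highest other was 17.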
